A study of Homo sapiens with 4 samples.

How the data were processed

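RNA was measured in H1299 cells, an established human non-small cell lung cancer line, after delivery of either a control virus or a virus that knocks down ZNF200, a zinc finger gene. The series holds 4 libraries, 2 per group, each from a single culture well. The control samples are labelled as wild type and unloaded, while the treatment text names a control virus, and they were taken as control virus; the value columns of the knockdown files are headed Z3, which no label explains. Per the labels, total RNA was the starting material; the library kit, its strand setting and the sequence of the knockdown and control inserts are not given in the sources used here, so antisense reads cannot be told from sense reads.

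The deposited values are FPKM, fragments per kilobase of gene scaled to library size, with 1 library per file, per the file headers. Per the submitters' processing notes, the tools were fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1 with the GRCh38 genome build. The annotation release behind the FPKM values is not given in the sources used here. Of the genes listed by Ensembl identifier in each file, 629 (3.1%) had no gene symbol.

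Sequencing depth was read back from the FPKM values. For a gene with few reads, the ratios between libraries are ratios of small whole numbers, and 1815 genes with FPKM up to 0.3 gave the relative depth of the libraries. Whole read numbers in all 4 libraries followed from the ratios for 10233 of the 10285 tested genes (99.5%), at a relative tolerance of 1e-08. Ratios leave a common factor open, which was taken from the gene length. For the remaining 52 the reads came from the gene length. The totals used for normalizing came out at 20479755 and 21264470 reads for control libraries 1 and 2, and at 21318335 and 18801768 reads for knockdown libraries 1 and 2. The total of control library 1 was the most frequent value over genes, shared by 2109 of 11320 with more than 20 reads and a known length. The other totals followed from the relative depth. Between 98.0% and 98.2% of these reads fell in the listed genes. These read numbers served to judge precision and for an alternative test, not for the main test.

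Replicates were compared before they were averaged. The chi-square per gene on the recovered reads was 2.27 between the control libraries and 1.91 between the knockdown libraries, above the value of 1 that sampling noise alone gives. No file was therefore a copy or a plain resampling of another, but these values cannot tell separate cultures from separate libraries of the same RNA. The 4 comparisons across groups gave 55.6 to 60.9 per gene.

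Genes with FPKM of at least 1 in at least 2 of the 4 libraries were tested, 10285 in all. Values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), comparing knockdown with control. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Changes given as a number followed by "-fold", and ratios of means, are ratios of the mean FPKM of the groups without the added 1, so they generally lie further from 1 than the log2 values of the same gene imply. On data simulated from the real gene means and depths, with 200 of 10278 genes changed, the fit recovered 78% of 1.25-fold, 96% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes. It made 13 false calls beside those, and 0 calls when no gene was changed. The simulation assumed a dispersion of 0.001 between replicates.

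Before the data were examined, 46 gene lists were fixed, together with the rule for the genes named. That rule took ZNF200, then the 15 called genes with the highest and the 15 with the lowest log2 fold change that had a symbol, a mean FPKM of at least 1 in either group and no overlap between groups. It also took the 2 called members with the highest and the 2 with the lowest log2 fold change in each list. Where a list had no called member, it took the 2 with the smallest p. Some genes that the rule took, and 1 list that was tested but not called by the camera test described next, are left out of the text. Lists with at least 5 tested members, 41 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated inter-gene correlation and limma's fry test were run beside it. With the correlation estimated, camera refers its statistic to the residual degrees of freedom, 2 here. That version therefore had little power, and a missing call there does not show that a list was unchanged. Fry's directional p asks whether the members of a list move, on balance, one way, and does not compare the list with other genes.

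Alternatives fixed in advance covered the filter on low values, the scaling between libraries, the pseudocount, the variance model, the thresholds, a replicate block and the omission of each library in turn. After the data had been seen, a limma voom fit on the recovered reads, a removal of the trend with GC content and gene length (loess, span 0.3), and a set test without list members that hold either of 2 short sites were added.

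Gene positions, gene lengths and sequences came from GENCODE release 29 on GRCh38, which may differ from the annotation behind the FPKM values. Short sequence sites were searched in the coding sequence and 3′ UTR of the transcript with the longest coding sequence of each gene. For this scan, 9923 tested genes with a 3′ UTR of at least 50 bases were used, and the log2 fold change was regressed on the presence of each hexamer or heptamer with linear and squared terms for log UTR length and GC content. Sites were chosen on odd-numbered chromosomes and tested on even-numbered chromosomes and X. On simulated fold changes the scan found a planted hexamer with a coefficient of -0.15 in 20 of 20 runs, and in 20 runs with nothing planted no chosen hexamer passed 4 standard errors on the second set of chromosomes. The simulated values were independent normal noise. In the real data the t values of hexamers on the second set had an SD of 1.39, so the same bound may be looser there. For gene groups, 10000 random lists were drawn from the 50 nearest genes in exon length, GC content and level. As a check, 9 of 200 random lists of 40 genes fell below the lower edge of the central 95% of their matched lists. More fell there than such an edge should leave, so the matched ranges may be somewhat narrow. Genes were also drawn singly, so the ranges leave out correlation within a list. That was estimated at 0.42 for cytosolic ribosomal proteins and 0.18 for oxidative phosphorylation. The scans and permutation tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.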

Results

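After delivery of a ZNF200 knockdown virus, H1299 cells had less ZNF200 RNA and different levels of many other transcripts than cells given a control virus. The highest fold changes included CPA4, a carboxypeptidase gene, HMGCS1, which makes HMG-CoA for cholesterol synthesis, and the G1 kinase gene CDK6. The lowest included POLDIP2, the Notch effector RBPJ and the chromatin gene HMGA1. Immediate early, ER stress and heat shock genes rose in most cases (15 of 19, 17 of 21 and 12 of 16 tested), and genes of the cytosolic ribosome, oxidative phosphorylation and the interferon response fell (43 of 46, 29 of 33 and 13 of 16 tested). These lists were called by camera at its preset correlation, and for each the adjusted p = 0.665 with an estimated correlation, which has little power with 2 libraries per group.

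ZNF200 (ENSG00000010539; GRCh38 chromosome 16, 3222325 to 3236221, minus strand, protein-coding) was lower in the knockdown libraries. Its FPKM was 2.22 and 2.06 in the control libraries and 1.55 and 1.39 in the knockdown libraries, or 2.14 ± 0.116 against 1.47 ± 0.114 (mean ± SD, n = 2 per group). The ratio of the means was 0.688. ZNF200 fell by 0.35 on the log2 scale (SE 0.071), with an adjusted p of 0.0036 (limma, Benjamini-Hochberg). This change was near that of a typical called gene. On the same scale, the median absolute change of called genes was 0.3, and 463 genes were called lower by at least 1.5-fold. With a limma voom fit on the recovered reads, the log2 fold change was -0.53. The recovered reads on the gene were 341 (95% Poisson interval 305.8 to 379.2) and 328 (293.5 to 365.5) in control, and 248 (218.1 to 280.9) and 196 (169.5 to 225.4) in knockdown. These intervals cover counting error only.

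The highest fold changes in the knockdown libraries belonged to CPA4 and to KRTAP2-3, a keratin-associated protein gene of a family with near-identical members. CPA4 rose from 1.32 ± 0.309 to 10.7 ± 0.534 FPKM, a log2 fold change of 2.34 (SE 0.091; n = 2 per group throughout). KRTAP2-3 rose from 2.46 ± 0.167 to 14.7 ± 0.5 FPKM. HMGCS1 went from 37.3 ± 2.11 to 145.0 ± 4.61 FPKM (log2 fold change 1.93). TULP3, a ciliary trafficking adaptor, rose 4.0-fold, and CDK6 rose 3.65-fold to 81.9 ± 0.722 FPKM. DUSP5, a phosphatase of ERK, rose 3.31-fold, PLK2 3.0-fold and TNRC6A, a scaffold of the microRNA silencing complex, 3.02-fold. The other named genes with the highest fold changes were AOX1, PTX3, KRT34, SCML2, BTG2, SGK1 and CMTM3, at log2 fold changes of up to 1.45 (AOX1). For the genes of low level KRT34 and BTG2, the log2 fold change was 1.39 and 1.33, against 2.20 for each with voom. Adjusted p for these 15 genes lay between 5.41e-08 and 7.97e-05 (limma).

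Among the genes that fell, POLDIP2 went from 36.1 ± 1.05 to 8.67 ± 0.736 FPKM, a log2 fold change of -1.94 (SE 0.054). RBPJ, the DNA-binding partner of the Notch intracellular domain, went from 10.7 ± 0.141 to 2.13 ± 0.24 FPKM. NRM, a gene for an inner nuclear membrane protein, was 4.18-fold lower, PROSER1 5.01-fold lower and BCKDK, the kinase that restrains branched-chain ketoacid breakdown, 4.63-fold lower. The mitochondrial genes MRPL34 and AK4 were 3.71-fold and 3.61-fold lower. HMGA1, an abundant chromatin architectural protein gene that has processed pseudogenes, went from 541 ± 13.6 to 167 ± 0.466 FPKM. SERTAD2, RFLNA, EMP3, SELENON, UHRF1, ACP1 and WASF2 had log2 fold changes between -1.66 and -1.44. UHRF1 recruits the maintenance DNA methyltransferase, and WASF2 acts in actin branching. Adjusted p for these 15 genes lay between 5.41e-08 and 1.02e-06 (limma). Of these 15 genes, 11 carried the heptamer ACATCCA or CGTTCCT in the coding sequence or 3′ UTR, against 4 of the 15 genes with the highest fold changes and 27.8% of genes not called; these heptamers were chosen after the values were seen, because genes that hold them in the 3′ UTR had lower fold changes.

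**Figure D1:**
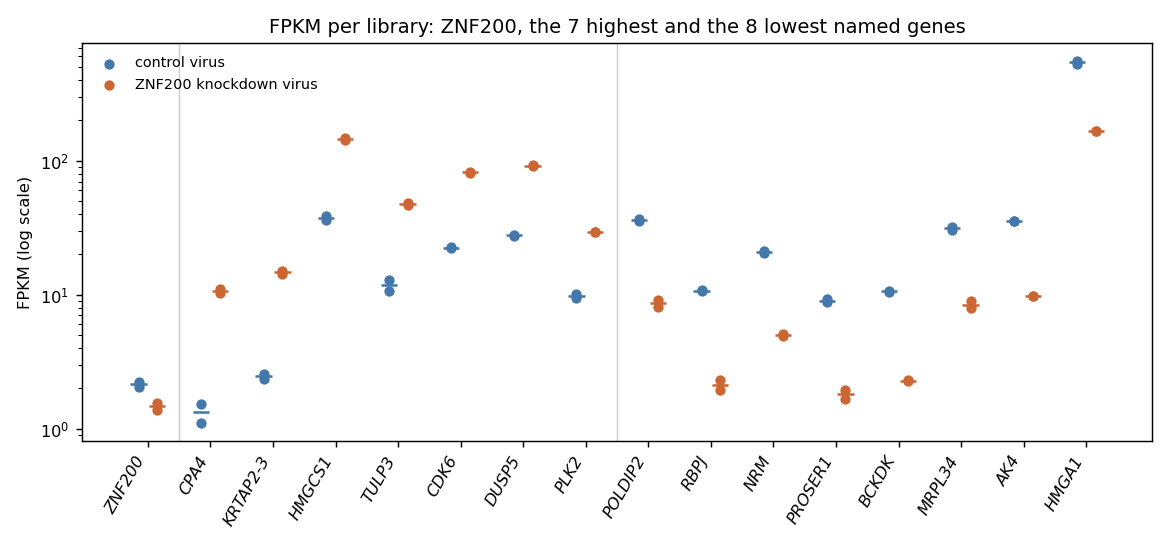
FPKM (log axis) of ZNF200, the 7 named genes with the highest and the 8 with the lowest log2 fold change in each of the 4 libraries, with control virus in blue and ZNF200 knockdown virus in orange. Each point is 1 library and each bar a group mean; for every gene drawn, both knockdown libraries lie on the same side of both control libraries, as the naming rule requires for all but ZNF200.

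Over all 10285 tested genes, 3190 were higher and 3169 lower in the knockdown libraries (limma, adjusted p under 0.05), or 61.8% of genes. Most of these changes were small. The median absolute log2 fold change of called genes was 0.3, while 46 genes rose and 83 fell by at least 1 on the log2 scale. In 81.4% of tested genes the 2 groups did not overlap, against 33.3% by chance.

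Of 41 lists tested, 7 were called higher and 6 lower by camera at its preset correlation, and 0 were called with an estimated correlation (smallest adjusted p = 0.665). High correlation alone does not account for the lost calls. Immediate early genes, with an estimated correlation of -0.043, went from p = 1.85e-05 to p = 0.0432 (camera, unadjusted). Stress and signalling genes made up most of the higher lists. Among immediate early genes, 15 of 19 tested members rose and 1 fell (adjusted over the list alone, 16 rose and 1 fell), with a list adjusted p of 0.000253. ATF3 rose from 2.21 ± 0.377 to 6.44 ± 0.065 FPKM and EGR1 from 12.5 ± 0.142 to 25.4 ± 1.82 FPKM, while KLF4 rose by 0.15 and NR4A2 fell by 0.24 on the log2 scale. In the ER unfolded protein response, 17 of 21 members rose and 2 fell (adjusted over the list alone, 17 and 2), with a list adjusted p of 0.000289. HSPA5, the main ER chaperone, went from 119 ± 0.547 to 229 ± 4.2 FPKM and HERPUD1 rose 2.02-fold, whereas XBP1, itself a transcription factor of this response, fell by 0.41 and CANX by 0.19 on the log2 scale. Of 16 heat shock genes, 12 rose and 2 fell (adjusted over the list alone, 12 and 2; list adjusted p of 0.00137). HSPA1A and HSPA1B rose by 0.97 and 0.87 on the log2 scale; they are near-identical copies, so reads could be split between them. HSPE1, a mitochondrial chaperonin gene, and DNAJB1 fell by 0.45 and 0.12. With an estimated correlation, the adjusted p = 0.665 for each of these 3 lists.

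Of 14 genes of the NF-kB and cytokine list, 11 rose and 2 fell (adjusted over the list alone, 11 and 2; list adjusted p of 0.00896). IL32 rose from 2.42 ± 0.326 to 6.58 ± 0.493 FPKM and BIRC3 from 21.7 ± 0.91 to 39.3 ± 0.088 FPKM, while CCL2 fell by 0.42 and LIF by 0.29 on the log2 scale. Without a filter on low values the list median was 0.18 instead of 0.49. YAP and TAZ targets had 15 of 21 members higher and 5 lower (adjusted over the list alone, 15 and 5; list adjusted p of 0.0141). CCN2, a matricellular growth factor gene, went from 83.6 ± 1.34 to 176 ± 0.077 FPKM and ANKRD1 rose 2.03-fold, whereas TEAD1 and AMOTL1 fell by 0.49 and 0.54 on the log2 scale. For both lists the adjusted p = 0.665 with an estimated correlation, and the YAP and TAZ call ended among genes with FPKM of at least 5 (adjusted p of 0.07). NRF2 targets had 12 of 19 higher and 4 lower (adjusted over the list alone, 12 and 5; list adjusted p of 0.035), with adjusted p = 0.665 with an estimated correlation. GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 1.83-fold and HMOX1 1.7-fold, while UGDH fell by 0.17 on the log2 scale. The call ended without a filter on low values (adjusted p of 0.175) and among genes with FPKM of at least 5 (adjusted p of 0.07). Cholesterol biosynthesis had 14 of 23 members higher and 5 lower (adjusted over the list alone, 14 and 5; list adjusted p of 0.0338), with adjusted p = 0.716 with an estimated correlation. HMGCS1 was among the members that rose, while TM7SF2, which acts later in the pathway, fell by 0.52 on the log2 scale. The call ended under quantile normalization (adjusted p of 0.0579) and among genes with FPKM of at least 5 (adjusted p of 0.0523).

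The lower lists were led by the translation and respiration machinery. Of 46 cytosolic ribosomal protein genes, 43 fell and 0 rose (adjusted over the list alone, 44 and 0), with a list adjusted p of 6.79e-10 and a median log2 fold change of -0.19 (-0.12 under quantile normalization). RPL15 went from 150 ± 2.38 to 97.1 ± 0.613 FPKM and RPL7A from 846 ± 25.1 to 622 ± 22 FPKM. RPL5 had a log2 fold change of -0.11, which was 0.06 under quantile normalization. Many of these genes have processed pseudogenes that could share reads. Oxidative phosphorylation genes of the nucleus fell in 29 of 33 cases and rose in 0 (adjusted over the list alone, 29 and 0; list adjusted p of 5.18e-07), with a median of -0.27. ATP5F1A, the alpha subunit of ATP synthase, went from 59.8 ± 1.33 to 29.2 ± 1.44 FPKM and NDUFB5, of complex I, fell by 0.52 on the log2 scale. ATP5F1B had a log2 fold change of -0.07, which was 0.12 under quantile normalization, and NDUFB3 one of -0.09. Of 24 genes of the TCA cycle and glutamine list, 12 fell and 2 rose (adjusted over the list alone, 12 and 2; list adjusted p of 0.0338). IDH2 fell by 0.45 on the log2 scale, while GPT2 rose by 0.22. With an estimated correlation, the adjusted p = 0.665 for each of these 3 lists. Transcripts of the mitochondrial genome did not form a called list: 3 of 13 rose, 1 fell (adjusted over the list alone, 3 and 0), the list adjusted p was 0.674, and MT-ND5, MT-ND6 and MT-ND1 rose by 0.27, 0.25 and 0.18 on the log2 scale, while MT-ND3 fell by 0.14. Their median was 0.011, and -0.058 without control library 2.

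Interferon response genes had the lowest median of the called lists, -0.5 on the log2 scale. Of 16 tested, 13 fell and 0 rose (adjusted over the list alone, 13 and 0; list adjusted p of 0.000429, and adjusted p = 0.665 with an estimated correlation). IFIT2 went from 3.28 ± 0.187 to 1.02 ± 0.083 FPKM and IFITM3 from 19.4 ± 0.254 to 12.1 ± 0.686 FPKM, while USP18 fell by 0.38 on the log2 scale. Without a filter on low values the list median was -0.13, and among genes with FPKM of at least 5 the call ended (adjusted p of 0.0523). Genes of G1/S and DNA replication fell in 19 of 33 cases and rose in 3 (adjusted over the list alone, 20 and 3; list adjusted p of 0.00173, and adjusted p = 0.665 with an estimated correlation). UHRF1 and E2F2 fell by 1.52 and 0.76, while CCNE1, the cyclin that starts S phase, rose by 0.67 and FEN1 by 0.50 on the log2 scale. The annotated set for the G1/S transition of the mitotic cell cycle leaned the other way, with 28 of 55 members higher and 10 lower, and was not called (adjusted p of 0.192). Of 26 homologous recombination and Fanconi genes, 16 fell and 1 rose (adjusted over the list alone, 16 and 1; list adjusted p of 0.0141, and adjusted p = 0.699 with an estimated correlation). XRCC3 and EXO1 fell by 0.58 and 0.57 on the log2 scale, BARD1 fell by 0.13, and RAD51AP1 rose by 0.11. The call ended among genes with FPKM of at least 5 (adjusted p of 0.07).

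The hexamers ACATCC and CGTTCC, chosen in the same way, were common in coding sequences and 3′ UTRs. Either was present in 59.0% of genes not called and 68.4% of genes called lower. Members with either hexamer made up 21 of the 33 G1/S genes and 13 of the 24 TCA genes searched. They made up 13 of the 26 recombination genes and 9 of the 18 NRF2 targets searched. These shares were not far from those of genes in general, so the lists did not stand out. Without such members, these 4 lists were no longer called, with adjusted p of 0.662, 0.234, 0.248 and 0.204 on 12, 11, 13 and 9 members. Their medians without such members were -0.06, -0.06, -0.13 and 0.15, against -0.14, -0.10, -0.18 and 0.15 with all members. With so few members left, a lost call does not show that the sites carried the list. Members with a site had lower medians than members without in the G1/S, TCA and recombination lists, at -0.32, -0.21 and -0.2. For NRF2 targets the members with a site had the higher median, 0.27. The NF-kB list had 3 members left, too few to test. The remaining 8 lists were called in the same direction without them. They included the ribosomal protein list, with 28 of 30 remaining members lower, and the oxidative phosphorylation list, with 17 of 20 lower. Apoptosis regulators and autophagy genes, not called with all members, were called higher without such members at the preset correlation (adjusted p of 0.0235 and 0.00526). With all members their adjusted p = 0.764 and 0.716 with an estimated correlation. The hexamers were chosen for low fold changes of their carriers, so leaving carriers out shifts the members that remain upward. Carriers stayed among the genes that each list was compared with, which further favours calls in the higher direction.

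**Figure D2:**
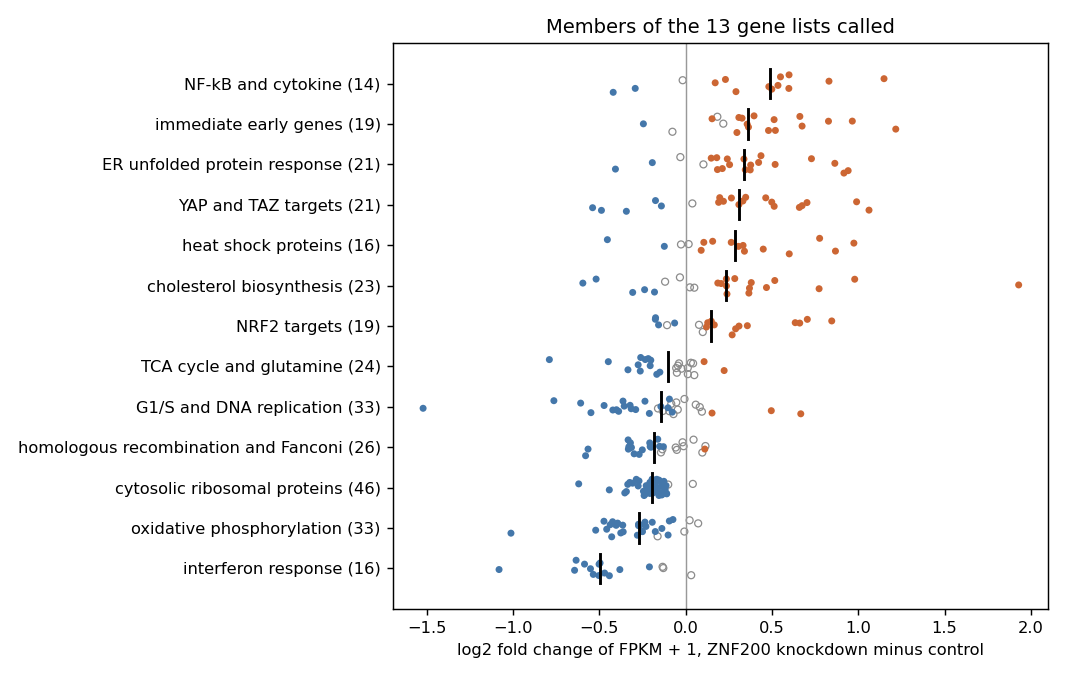
Log2 fold change of FPKM + 1, ZNF200 knockdown minus control, of every tested member of the 13 called lists, with the number of members in brackets. Filled points are called genes (orange higher, blue lower), open points are genes not called, and black bars are list medians, which run from -0.5 for interferon response to 0.49 for NF-kB and cytokine.

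Cell cycle arrest and death genes changed individually without a list called by camera, while fry, which does not compare with other genes, called the 4 lists given here (adjusted p of 0.0119 for CDK inhibitors, 0.041 for apoptosis, 0.017 for G2/M and 0.00713 for histones). The list of CDK inhibitors and senescence-associated genes had 6 of 11 higher and 2 lower (adjusted over the list alone, 6 and 2; list adjusted p of 0.191), with CDKN2C and GLB1 lower. CDKN1A, the p21 inhibitor gene, went from 22.9 ± 0.234 to 52.2 ± 1.14 FPKM. Of 25 apoptosis regulators, 13 rose and 8 fell (adjusted over the list alone, 13 and 9; list adjusted p of 0.545). BIK rose 2.96-fold, while CASP2 fell by 0.77 and BAD by 0.61 on the log2 scale. G2/M and mitosis genes had 15 of 29 lower and 4 higher (adjusted over the list alone, 16 and 4; list adjusted p of 0.12), with CENPA and CDC20 lower by 0.54 and 0.43 and ANLN and KIF23 higher. Of 14 replication-dependent histone genes, 8 fell and 2 rose (adjusted over the list alone, 8 and 2; list adjusted p of 0.187). H3C2 and H2AC13 fell, and H2BC21 and H2BC8 rose; histone genes are near-identical copies and their levels are uncertain.

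Adhesion, differentiation and pathway lists held changes in both directions, and camera called none of them. Fry called the epithelial (adjusted p of 0.0266), TGF-beta (0.0327) and receptor tyrosine kinase (0.041) lists higher and the Wnt (0.0145) and Notch (0.0461) lists lower, but not the EMT, matrix and MAPK lists. Of 14 mesenchymal and EMT genes, 7 rose and 3 fell (adjusted over the list alone, 7 and 3; list adjusted p of 0.486). VIM, which encodes vimentin, went from 189 ± 0.32 to 121 ± 0.543 FPKM and MMP14 fell by 1.09, while ZEB2 and ITGA5 rose by 0.73 and 0.56 on the log2 scale. Of 8 epithelial junction and keratin genes, 4 rose and 3 fell (adjusted over the list alone, 4 and 3; list adjusted p of 0.591), with DSP and TJP1 higher and KRT8 and PKP3 lower. Of 22 matrix, integrin and migration genes, 10 rose and 7 fell (adjusted over the list alone, 10 and 8; list adjusted p of 0.746), and the median was above 0 while fry gave the lower direction. CD44 went from 48.8 ± 0.256 to 25.1 ± 0.098 FPKM and PLAU fell by 0.69, while LAMB3 and ITGB1 rose by 0.64 and 0.47 on the log2 scale. Of 16 TGF-beta and BMP response genes, 8 rose and 4 fell (adjusted over the list alone, 8 and 4; list adjusted p of 0.326), with the BMP targets ID1 and ID3 lower by 1.03 and 0.81 and CCN2 higher. The Notch list had 5 of 12 higher and 4 lower (adjusted over the list alone, 5 and 4; list adjusted p of 0.829), with a median of 0.03, a mean of -0.12 and the lower direction in camera. Among genes with FPKM of at least 5 the Notch median was -0.58, and without knockdown library 2 it was -0.06. HES1, a Notch target, fell by 0.75 on the log2 scale, while HEY2 and JAG2 rose. Of 8 Wnt targets, 3 rose and 3 fell (adjusted over the list alone, 3 and 3; list adjusted p of 0.703), with MYC and NKD2 higher and LEF1 lower beside CD44. The Wnt median was -0.04, and 3 of 14 alternatives turned its sign. Of 15 MAPK feedback genes, 9 fell and 3 rose (adjusted over the list alone, 9 and 4; list adjusted p of 0.326), with SPRY1 and EMP1 lower and SPRED1 higher beside DUSP5. Receptor tyrosine kinases and ligands had 5 of 13 higher and 5 lower (adjusted over the list alone, 6 and 5; list adjusted p of 0.591), with FGFR1 and HBEGF higher and TGFA and INSR lower.

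Metabolic, autophagy and detoxification lists outside those called by camera held changes in both directions too. Fry called the ATF4 (adjusted p of 0.0497), ferroptosis (0.00713) and autophagy (0.024) lists higher and the fatty acid oxidation list (0.0128) lower, but not the other 5 lists given here. The ATF4 and amino acid response had 11 of 22 higher and 6 lower (adjusted over the list alone, 12 and 7; list adjusted p of 0.434), with STC2 and SLC7A11 higher by 0.89 and 0.66 and DDIT4 and PSAT1 lower. Hypoxia targets had 7 of 15 higher and 1 lower (adjusted over the list alone, 7 and 1; list adjusted p of 0.12), with ADM, ANGPTL4 and INSIG2 higher and HIF1A lower by 0.28. Glycolysis genes had 8 of 20 lower and 5 higher (adjusted over the list alone, 8 and 5; list adjusted p of 0.326), with PKM and GPI lower and PFKFB3 and SLC16A1 higher. Fatty acid synthesis had 9 of 22 higher and 6 lower (adjusted over the list alone, 9 and 6; list adjusted p of 0.591), with ELOVL7 and ACSL4 higher and FADS1 and SCD lower. Fatty acid oxidation had 6 of 17 lower and 2 higher (adjusted over the list alone, 5 and 2; list adjusted p of 0.222), with CRAT and HADHA lower and PPARA and CPT1A higher. Ferroptosis and iron genes had 10 of 20 higher and 5 lower (adjusted over the list alone, 11 and 5; list adjusted p of 0.191), with SAT1 and HMOX1 higher by 1.04 and 0.70 and FTH1, which has processed pseudogenes, and GCH1 lower. Autophagy and lysosome genes had 12 of 29 higher and 5 lower (adjusted over the list alone, 12 and 5; list adjusted p of 0.191). SQSTM1, the p62 autophagy receptor gene, went from 42.9 ± 0.532 to 91.8 ± 2.63 FPKM and GABARAPL1 rose, while ATP6V0D1 and ATG12 fell. Ribosome biogenesis and MYC targets had 15 of 31 higher and 8 lower (adjusted over the list alone, 15 and 9; list adjusted p of 0.368), with ODC1 and TFAM higher and SRM and CAD lower. Of 10 drug efflux and detoxification genes, 3 rose and 4 fell (adjusted over the list alone, 3 and 4; list adjusted p of 0.829), with ABCB1 and ABCC5 higher and ALDH3B1 and CYP1B1 lower. Their median was -0.04 and their mean 0.0082, and camera gave the lower direction; 2 of 14 alternatives turned the sign of the median.

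Chromatin lists linked to zinc finger genes were not called by camera, while fry called the KRAB repressor list (adjusted p of 0.0119) and the neighbours of ZNF200 (adjusted p of 0.041), both lower. Of 22 chromatin repressors that work with KRAB zinc fingers, 6 rose and 5 fell (adjusted over the list alone, 6 and 5; list adjusted p of 0.973), with a median of 0.0033, a mean of -0.05 and the lower direction in camera, and 3 of 14 alternatives turned the sign of the median. The heterochromatin protein genes CBX3 and CBX5 went from 57.8 ± 0.437 to 23.3 ± 0.177 FPKM and from 33.7 ± 0.303 to 15.9 ± 0.308 FPKM, while CBX1 and DNMT3B rose by 0.44 and 0.70 on the log2 scale. Of 12 protein arginine methyltransferases and partners, 2 rose and 3 fell (adjusted over the list alone, 2 and 3; list adjusted p of 0.635), with WDR77 and PRMT6 higher and CARM1 and COPRS lower. Among 11 tested neighbours of ZNF200 on 16p13.3, 2 rose and 4 fell (adjusted over the list alone, 2 and 4; list adjusted p of 0.627), with ZNF597 and IL32 higher and NAA60 and HCFC1R1 lower. Antigen presentation genes had 6 of 12 lower and 3 higher (adjusted over the list alone, 6 and 3; list adjusted p of 0.486; fry adjusted p of 0.0119, lower), with TAP2 and PSMB9 lower by 0.83 and 0.79 and HLA-E and HLA-B higher; HLA genes have close paralogs.

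Markers of fibroblasts, immune cells and endothelial cells were scarce in these cultures. Of 13 fibroblast markers only S100A4 passed the filter, and it fell by 0.58 on the log2 scale (adjusted over the list alone, 1 fell). Of 15 immune markers only ITGAM passed, at 1.01 ± 0.194 and 1.75 ± 0.074 FPKM, and it rose (adjusted over the list alone, 1 rose). Of 10 endothelial markers only ENG passed, at 1.36 ± 0.08 and 1.49 ± 0.144 FPKM, with an adjusted p of 0.388 (limma), and it was not called over the list alone either. Of 21 surfactant and lung lineage genes 4 were tested, with FOXA1 higher and ABCA3 lower (adjusted over the list alone, 1 and 2); 2 of 14 alternatives turned the sign of their median. Of 18 neuroendocrine markers 7 were tested, and 3 rose and 4 fell (adjusted over the list alone, 3 and 4, with a camera list adjusted p of 0.834). The neuronal repressor REST and UCHL1 were higher, and CHGB and SYP lower. UCHL1 was abundant, at a mean of 328 FPKM in control and 402 FPKM in knockdown. The list of abundant nuclear RNAs had 1 tested member, TUG1, which rose by 0.24 (adjusted over the list alone, 1 rose).

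The test was limma on log2(FPKM + 1), with 2 libraries per group. Recovered depth ran from 18801768 to 21318335 reads per library, and 10132 to 10158 genes per library had FPKM of at least 1. The SD of the log2 difference was 0.098 between the control libraries and 0.097 between the knockdown libraries, against 0.346 to 0.347 across groups. The labels do not say whether the wells were transduced separately, so p-values measure only the spread between these samples, which may be technical. With 2 libraries against 2, an exact permutation test of a single gene could not go below p = 0.333 (two-sided), so calls rest on the spread that limma pools over genes.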

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

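The limma voom fit, the removal of GC and length trends and the set test without members holding ACATCC or CGTTCC were chosen after seeing the data; the other alternatives were fixed in advance. ZNF200 was lower and called in each of the 13 alternatives that tested it, with log2 fold changes from -0.53 (voom) to -0.3; leaving out each library in turn gave -0.39 to -0.3, and the filter of FPKM at least 5 in 2 libraries left it untested. Without 1 library, where the lone library is assumed to vary like the other group, 2680 to 2929 genes were higher, 2669 to 2924 lower and 13 to 14 lists called. At an absolute log2 fold change of at least 1, 46 genes were higher and 83 lower. The replicate block gave 3160 higher and 3190 lower genes, 13 lists and a ZNF200 change of -0.35. Same-numbered libraries did not deviate together (r = -0.028 across genes), so no pairing by number was seen. That does not show that same-numbered wells were handled apart. List calls depended on the setting too. At FPKM of at least 5, where fewer members are tested, 8 were called. With fry, which asks a different question, 30 were called, and with an estimated correlation, which has little power here, 0. Of the camera calls, NRF2 targets were also lost without a filter, and cholesterol biosynthesis under quantile normalization. Quantile normalization called 4 genes in the opposite direction, and it turned 2 named genes, RPL5 to 0.057 and ATP5F1B to 0.12; the cause was not tested. Of the values of named genes under alternatives, 2531 kept their call and direction and 64 no longer passed the threshold, none of them among the 15 genes with the highest or lowest fold changes. The share of called genes that were higher stayed between 48.9% and 52.7%. Alternatives planned for count tables do not apply to FPKM files. Without a filter on low values, 3079 of 16122 genes were higher and 2912 lower. Whether a well-to-well difference contributes is beyond what these 4 libraries resolve.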

Other observations

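All tests in this part were chosen only after the results had been seen; for the matched random lists alone, the bounds were written before their own result was known. Gene names outside the fixed rule were chosen after their values were seen. The gene sets annotated in the files add base excision repair to the lower groups. Of 30 tested members, 16 fell and 2 rose, with a median log2 fold change of -0.17 (camera adjusted p of 0.0458 over 297 pathways, and adjusted p = 0.829 with an estimated correlation). UNG, which removes uracil from DNA, fell by 0.82 on the log2 scale, PCNA by 0.55, APEX1, the abasic site endonuclease, by 0.53 and LIG1 by 0.50. FEN1 and SMUG1 rose by 0.50 and 0.16. Mismatch repair had 14 of 21 lower and 3 higher, without passing the adjustment (adjusted p of 0.0869, and 0.829 with an estimated correlation).

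Of the higher groups in the same annotation, the IL-17 signalling pathway had 27 of 46 members higher and 5 lower (camera adjusted p of 0.027, and adjusted p = 0.829 with an estimated correlation). JUN rose by 0.83, CEBPB by 0.61 and TNFAIP3 by 0.55 on the log2 scale; part of these genes also stand in the fixed lists. Leukocyte cell-cell adhesion had 10 of 12 members higher and 0 lower (adjusted p of 0.0363 over 1882 processes, and adjusted p = 0.996 with an estimated correlation), with ICAM1 higher by 0.60 and NT5E by 0.33. Among single genes known from microRNA processing or silencing, DICER1 rose by 0.86 and AGO2 by 0.49 on the log2 scale, beside TNRC6A at 1.48, while AGO1 fell by 0.32 (adjusted p of 0.0016, limma). The related annotated set, silencing by microRNA through inhibition of translation, was not called (adjusted p of 0.261, and adjusted p = 0.996 with an estimated correlation). LIN28B, a repressor of let-7 processing, went from 33.3 to 78.6 FPKM.

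Many genes lower in knockdown carried particular short sites. Among 4096 hexamers, the lowest on odd-numbered chromosomes was ACATCC and the next without a shared run of 4 bases was CGTTCC; on even-numbered chromosomes and X these had coefficients of -0.138 (SE 0.013) and -0.167 (SE 0.019) and ranked 1 and 2. The heptamers ACATCCA and CGTTCCT, chosen the same way, mark both ends of AGGAACGACTAAATACATCCA, a stretch of the ZNF200 coding sequence read on opposite strands (GRCh38 chromosome 16, minus strand, exon 5 of 5). Such a pair within 25 bases occurred in 2 of 19383 transcripts, ZNF200 and COL22A1. A candidate explanation is microRNA-like pairing of both strands of a hairpin aimed at this stretch with other transcripts. Direct pairing with these sites is not the whole cause, since 31.6% of genes called lower had neither hexamer. A hexamer was also present in 59.0% of genes not called and 51.7% of higher genes, and site counts added 5.7% to the variance explained. Among genes lower by at least 1 on the log2 scale, sites were more frequent. On even-numbered chromosomes and X, 88.6% of 44 such genes had a hexamer, against 59.2% of genes not called there. These counts do not cover genes that changed in turn after a gene with a site. GC content and length over all annotated exons are not the whole cause either, since 2875 of 3169 lower calls stayed with that trend removed. The length of the transcripts present in these cells was not tested. What loss of ZNF200 itself contributes cannot be told apart with 1 knockdown construct, as 24.0% of genes with neither hexamer were also called lower, against 35.2% of genes with a hexamer, and no second hairpin or rescue was among the samples.

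Genes with sites of microRNA families that are known to be broadly expressed tended to be higher in knockdown; no microRNA was measured in these cells, and the families were sorted by general knowledge. The site coefficient was 0.053 (SE 0.010) for miR-29 and 0.042 (SE 0.010) for miR-19, but -0.034 (SE 0.011) for miR-7, also broad, and 0.072 (SE 0.026) for miR-208, a restricted family, and 19 of 22 broadly expressed families had coefficients above 0, against 10 of 15 tissue-restricted families. The mean t of the broad families was higher by 1.69 (permutation p = 0.011, two-sided). At an equal coefficient, t is larger for a site that more genes hold. Restricted sites included those of miR-375 and miR-208, in 94 and 177 genes, while each broad site was in 839 or more. The difference can therefore reflect site frequency as well as effect, and weaker repression by endogenous microRNAs remains only a candidate explanation. Several of these sites share bases, so the families are not independent. A site of the control hairpin, whose sequence is not given in the sources used here, remains open. The highest heptamer on odd-numbered chromosomes, AAGAGCA, had a coefficient of 0.056 (SE 0.016) on the others, but the highest hexamer, AAGAGC, only 0.020 (SE 0.013).

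The lower ribosomal protein and oxidative phosphorylation transcripts were set against 3 technical explanations. Lists of genes near in exon length, GC content and level had medians whose central 95% reached down to -0.10 for ribosomal and -0.12 for respiratory genes. The observed -0.19 and -0.27 lay below, and 0% of 10000 such lists were as low. For ribosomal genes the match in level was incomplete (median FPKM of 195 against 145), so an effect of level is not fully excluded for them. Exon length covered all annotated exons of a gene, with medians of 3667 bases for ribosomal and 2838 for respiratory genes. The length of the transcripts present in these cells was not matched, so an effect of transcript length was not tested. Members with neither hexamer had medians of -0.19 and -0.25, which argues against direct hairpin sites as the cause. Over the 14 alternative fits, only some of which changed the scaling, the medians nearest to 0 were -0.12 and -0.26. These values argue against scaling between the libraries as the whole cause. For ribosomal genes the -0.12 came from quantile normalization, so part of their fall depended on the scaling. What lowered these transcripts is left open.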
